A study of Mus musculus with 8 samples.

How the data were processed

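RNA from L929 cells, a mouse fibroblast line, and from L929 cells that carry ectopic IRF8 (L929IRF8 below) was hybridised to Illumina mouse bead arrays, with and without interferon beta (IFNβ). Per the labels, treated cells received 1000 U/ml IFNβ for 4 h, and each of the 4 groups has 2 independent replicates, which gives 8 arrays. The labels do not say how the ectopic IRF8 was introduced, whether the line is a clone, or whether the parental cells carry an empty vector. How many arrays there are limits the precision of every value.

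The deposited values are linear intensities of 25697 probes on each array. No processing tool is given in the sources used here. From the values themselves, the deposited intensities had been background-subtracted, since 28.1% to 28.3% of the probes on an array lie below 0, and quantile normalized, since the sorted values of the 8 arrays differ by at most 1.7 intensity units. They were therefore not normalized again. Quantile normalization forces each array onto one distribution, so a change shared by most genes would not be visible. No detection p-values, slide or scan information was used here. The lowest deposited value was -23.7, and 23.7 intensity units served as the bound of background. A group with both arrays at or under that bound has only an upper limit, so a fold against it is given as "at least". Folds between 2 groups are ratios of geometric means over the arrays of each group, with values under the bound raised to it. No fold is given where both groups lie under the bound. On each array, 44.3% to 44.4% of the probes exceeded the bound, and 11411 probes exceeded it in the mean over the 8 arrays.

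Probes were named from the platform annotation given with the series. Of the probes, 23978 have 1 gene symbol, 0 have several and 1719 have none, which gives 16593 genes. Entrez IDs of 23962 named probes were found in the RefSeq gene table, and 0 symbols changed. For the 4777 genes with more than 1 probe, the representative probe is the one with the highest mean log2 value over the 8 arrays. No genomic coordinates are given, because the sources used here do not tie the probes to a genome build.

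Intensities below 0 were set to 0, 16 was added, and log2 was taken, so that changes of dim genes are understated. A linear model with 1 coefficient for each of the 4 groups was fitted to all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no replicate block and no filter. The fit has 4 residual degrees of freedom, to which eBayes added 0.684. Adjusted p-values are those of limma's moderated test after Benjamini-Hochberg adjustment over all 25697 probes, with a threshold of 0.05. The 5 comparisons were L929IRF8 against L929 in untreated cells, IFNβ against untreated in each line, L929IRF8 against L929 after IFNβ, and the difference between the lines' IFNβ effects (the interaction). An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333. Errors are SDs over the 2 arrays of a group for intensities and standard errors (SE) from limma for log2 changes. The p-values of single probes measure the spread between these arrays.

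A set of 22 gene lists with 512 entries, 456 of them on the array, was fixed before the data were examined: ISGF3 antiviral genes, GBP and IRG GTPases, MHC class I presentation, MHC class II presentation, chemokines and cytokines, nucleic acid and pattern sensing, the IRF family, interferon receptor and JAK-STAT, IRF8-activated genes of myeloid cells, myeloid markers, lymphoid markers, epithelial and endothelial markers, fibroblast and matrix genes, cell cycle, apoptosis, NF-kB targets, unfolded protein and amino acid stress, cholesterol synthesis, glycolysis and hypoxia, immediate early genes, p53 targets and housekeeping genes. Few genes stand in more than 1 list; the largest overlap is 5 genes, between the chemokines and the NF-kB targets. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, on representative probes. P-values were adjusted over the 22 lists of a comparison, and camera was run again with an estimated correlation. At the preset correlation it sets a list's genes against the other genes, so its p-values do not measure the spread between arrays. The estimated correlations were 0.182 for the ISGF3 antiviral genes, 0.158 for the GBP and IRG GTPases and 0.491 for MHC class I presentation. With an estimated correlation camera also uses the 4 residual degrees of freedom, so a lost call need not come from correlation. Members are counted as risen or fallen by their adjusted p over all probes.

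The genes named were chosen by a rule fixed before the data were examined. For each comparison it takes the 10 largest rises and the 10 largest falls among genes that passed and whose arrays do not overlap between the groups, and, where fewer than 3 passed in a direction, the 5 with the smallest p, named as not passing. For the interaction, the effects must differ the same way under both replicate numbers. The rule adds up to 4 members of each list with the largest change, and Irf8. Any gene chosen otherwise is said to have been chosen after its values were seen.

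The steps were tested on simulated intensities made from the real probe means and spreads, with 100 probes changed 2-fold and 100 changed 4-fold. Noise was drawn independently for each array around 1 mean per probe, with no shift shared by replicate number and no other group differences. The shares called and the false calls therefore need not match those in the data. For the IFNβ effect in L929, 22% of the 2-fold and 55% of the 4-fold changes were called, with 23 false calls among all other probes, 3 of them above background. For L929IRF8 against L929 after IFNβ these were 17% and 48%, with 40 false calls, 6 of them above background. For the interaction they were 12% and 24%, with 23 false calls, 4 of them above background. Most false calls thus fell on probes near the floor of 0. With only the 11411 probes above background in the fit, 36% and 78% of the changes were called for the IFNβ effect in L929 with 4 false calls, 32% and 72% for the lines after IFNβ with 8, and 11% and 51% for the interaction with 4. The list test called 10 of 10 simulated lists shifted by -0.5 and 0 of 10 unshifted ones. The simulated list members were above background and uncorrelated, so false calls on lists of correlated genes were not tested.

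Alternatives fixed in advance were median centring of each array, an offset of 1, only probes at or above the median in brightness, an intensity trend in eBayes, the replicate number as a block, only the groups compared, a change of at least 2-fold, 1 probe per gene, and leaving out each array. For the lists they were an estimated correlation, median centring, the mean of a gene's probes, fry, the block and leaving out each array. A fit restricted to the probes above background, a test restricted to interferon-induced genes and the line difference averaged over both treatments were added after the data had been seen.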

Results

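Gene expression was measured in L929 mouse fibroblasts and in L929 cells with ectopic IRF8, a transcription factor of the interferon regulatory factor family that is normally found in immune cells. Each line was left untreated or given IFNβ at 1000 U/ml for 4 h, with 2 arrays in each of the 4 groups. The median intensity was 13.8 or 13.9 and the highest 31689 on each array. Pearson correlations of log2 values between the arrays of one group were 0.9891 to 0.9915, and between arrays of the different lines under the same treatment 0.9885 to 0.9933. In a principal component analysis, the first component (66.7% of the variance) separated the IFNβ arrays from the untreated arrays, and the second (15.2%) separated replicate 1 from replicate 2.

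Irf8 has 1 probe on the array, ILMN_2673369. It read between -2.3 and 7.8 intensity units on all 8 arrays, below the background bound of 23.7, in the lines with and without ectopic IRF8 alike. The labels do not describe the construct. A probe outside the introduced sequence would not detect it, and whether this probe lies outside is not known. The values therefore neither show ectopic IRF8 in L929IRF8 nor exclude it.

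The first question was how L929 cells respond to IFNβ. After 4 h, antiviral effector genes rose from background to some of the brightest signals on the array. Rsad2, which encodes the antiviral enzyme viperin, went from 3.60 ± 0.707 to 17650 ± 2590 (SD, n = 2 each), at least 741-fold. Cxcl10, a chemokine that attracts T cells, rose at least 302-fold, Oasl2 at least 280-fold and Igtp, an immunity-related GTPase, at least 381-fold. Isg15, a ubiquitin-like modifier, rose 295-fold from 28.3 ± 2.55 to 8362 ± 1070. In the limma fit 328 probes passed, 256 higher and 72 lower, and 211 of the higher but only 2 of the lower ones changed at least 2-fold. At the unadjusted level 2538 probes had p under 0.05, against 1284.9 expected by chance.

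Of the 41 ISGF3 antiviral genes, the classical targets of the transcription factor that type I interferon activates, 30 rose, 0 fell and 11 did not pass, with a median log2 change of 3.05 (2.89 with values raised to the background bound). Adjusted over the list alone, 37 rose. Beside Rsad2 they include Ifit3 (19420 ± 3170 after IFNβ), Usp18 (16180 ± 627) and Oasl2 (6634 ± 249), each with an untreated mean under the background bound. Of the 18 GBP and IRG GTPases, which act against intracellular pathogens, 13 rose (16 adjusted over the list alone), with a median of 4.40 (3.76 with values raised to the bound). Irgm2 rose at least 260-fold, Gbp3 at least 158-fold and Gbp2b at least 121-fold. Both lists passed camera (adjusted p = 4.48e-65 and 1.45e-29) and also with an estimated correlation (adjusted p = 0.0213 for each).

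Part of the MHC class I genes rose too. Of the 21 MHC class I presentation genes 6 rose (16 adjusted over the list alone), among them the peptide transporter Tap1 (13.8-fold), the immunoproteasome subunit Psmb10 (7.07-fold) and the class I regulator Nlrc5 (7.22-fold). Camera gave an adjusted p of 7.18e-20, with adjusted p = 0.112 with an estimated correlation. Of the 23 nucleic acid and pattern sensing genes 9 rose (12 adjusted over the list alone). They include the RNA sensors Dhx58 (at least 67.3-fold), Ddx58 (at least 58.1-fold) and Tlr3 (at least 18.3-fold), and the DNA exonuclease Trex1 (8.21-fold). This list passed camera (adjusted p = 1.34e-17) and with an estimated correlation (adjusted p = 0.0141). In the IRF family list 5 of 9 members rose: Irf7 at least 24.0-fold, Irf9 10.4-fold, Irf1 7.89-fold, Irf5 at least 7.31-fold, and Irf2. Adjusted over the list alone, 5 rose and 2 were lower, Irf2bp1 and Irf2bpl, which encode IRF2-binding proteins rather than IRFs. The list had a camera adjusted p of 1.57e-05, and an adjusted p of 0.0483 with an estimated correlation.

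Among 32 chemokines and cytokines 7 rose (10 adjusted over the list alone, with 2 lower), led by Cxcl10, Il15 (15.1-fold) and Il6 (at least 5.02-fold). The list's median change was 0.10, but 0.00 without L929 IFNβ replicate 1, 0.16 and 0.40 without L929 untreated replicates 2 and 1, and 0.58 without L929 IFNβ replicate 2. Its adjusted p of 5.58e-07 became an adjusted p of 0.0721 with an estimated correlation. Of the 22 interferon receptor and JAK-STAT genes, Batf2 (46.9-fold) and Stat2 (23.3-fold) rose and the median was 0.03 (adjusted p = 0.0338, and adjusted p = 0.141 with an estimated correlation; 3 higher and 2 lower adjusted over the list alone). That call was lost with the replicate block (adjusted p = 0.0552) and without either untreated L929IRF8 array (0.059), L929 IFNβ replicate 1 (0.0891) or 2 (0.186), or L929 untreated replicate 2 (0.107). In the apoptosis list, which did not pass, Daxx (14.9-fold), Casp4 (4.88-fold) and Casp1 (2.09-fold) rose.

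Falls after IFNβ in L929 were small. Clec2e, a lectin-like gene, went from 122.6 ± 18.0 to background, at least 5.15-fold lower. Get1 and Abi2 were each 1.95-fold lower, Chst1 and Ahdc1 1.93-fold, Lrp6, a Wnt coreceptor, 1.94-fold, Trib2 1.80-fold and Spast 1.77-fold. Calml3 and Lrrc75b also passed, but both groups lay under the background bound. The cell cycle list was lower by camera (median log2 change -0.17, adjusted p = 0.000372) with 0 of its 29 members passing, also adjusted over the list alone, and adjusted p = 0.0533 with an estimated correlation. Of the probes called, 25 higher and 29 lower ones had both group means under background. Restricted to the 11411 probes above background, a fit added after the data were seen, 329 rose and 42 fell, 240 (without L929 untreated replicate 2) to 359 in all when any 1 array was left out. With the replicate block this restricted fit called 678 probes. Over all probes the count was 217 without either untreated L929IRF8 array.

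**Figure D1:**
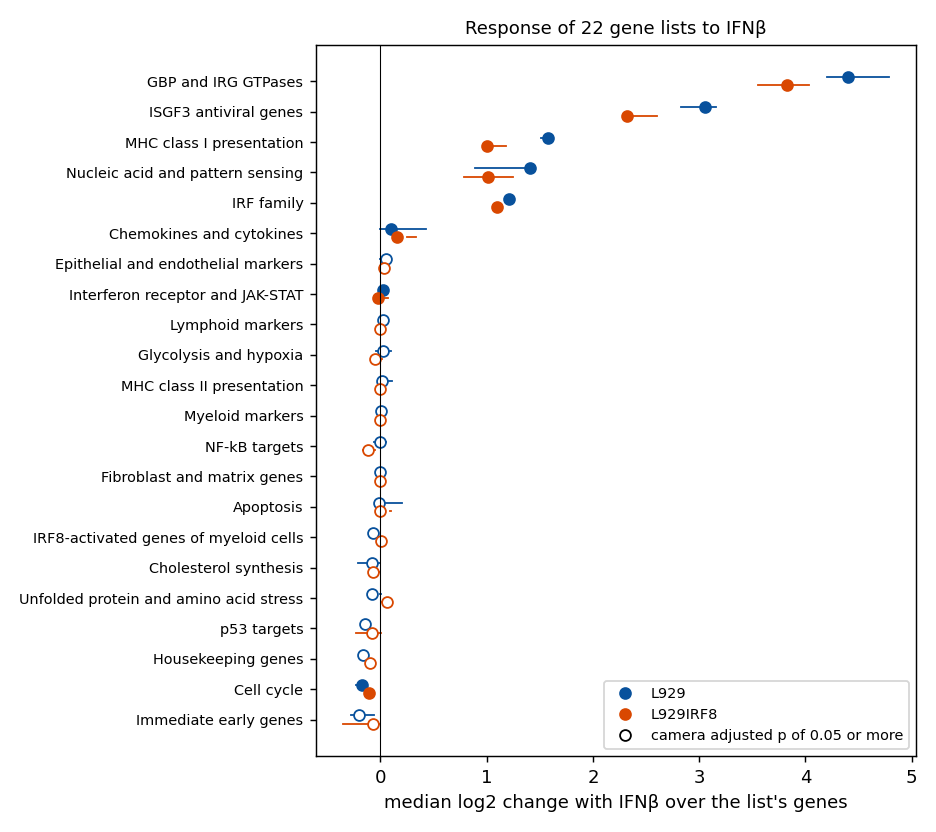
Median log2 change with IFNβ over the genes of each of the 22 lists (x axis, log2 scale) in L929 (blue) and L929IRF8 (orange). Points are the medians of the fitted changes, bars run between the medians of replicate 1 and replicate 2, and filled points passed camera; the GBP and IRG GTPases have the highest medians, 4.40 in L929 and 3.82 in L929IRF8.

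The same treatment of L929IRF8 cells raised largely the same genes. Rsad2 rose at least 352-fold to 8790 ± 3920, Usp18 at least 542-fold, Ifit3 at least 508-fold, Oasl2 at least 244-fold, Cxcl10 at least 194-fold and Oasl1 at least 123-fold. Igtp (6694 ± 1430 after IFNβ), Irgm2 (4564 ± 177), Isg15 (6304 ± 440) and Parp14 (4297 ± 735) rose too, from untreated values that lay partly under the background bound, so no fold is given. In the limma fit 276 probes passed, 222 higher and 54 lower, and 178 and 4 of these changed at least 2-fold. The unadjusted p was under 0.05 for 2514 probes. The count was 135 without either untreated L929 array and 526 without L929IRF8 IFNβ replicate 2. With the probes above background alone, 291 rose and 33 fell, 212 (without L929IRF8 IFNβ replicate 1) to 295 in all when any 1 array was left out and 645 with the replicate block.

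Of the ISGF3 antiviral genes 26 rose in L929IRF8 (36 adjusted over the list alone; median 2.32, or 2.49 with values raised to the bound; adjusted p = 9.54e-63, and adjusted p = 0.0235 with an estimated correlation). Of the GBP and IRG GTPases 12 rose (14 adjusted over the list alone; median 3.82, or 3.21 at the bound; adjusted p = 4.5e-28, and adjusted p = 0.0235 with an estimated correlation), including Ifi47 (at least 127-fold) and Gbp3 (at least 63.3-fold). In MHC class I presentation 4 rose, Nlrc5 (5.12-fold), Psmb9 (5.40-fold), Psmb10 and H2-M3, and 10 adjusted over the list alone (adjusted p = 4.48e-17, and adjusted p = 0.133 with an estimated correlation). In nucleic acid and pattern sensing 10 rose (11 adjusted over the list alone), among them Dhx58 (at least 46.2-fold), Ddx58 (at least 35.9-fold), Tlr3 (at least 13.3-fold) and Ifi205 (at least 7.16-fold), with an adjusted p of 9.53e-16 and an adjusted p of 0.0177 with an estimated correlation.

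In the IRF family 4 of 9 genes rose in L929IRF8, Irf7 (at least 17.5-fold), Irf9 (8.32-fold), Irf1 (7.71-fold) and Irf2 (adjusted p = 2.49e-05, and adjusted p = 0.052 with an estimated correlation). Adjusted over the list alone, 5 were higher and 1, Irf2bp1, was lower. Of the chemokines and cytokines 6 rose (9 adjusted over the list alone), with Il6 at least 7.37-fold higher (adjusted p = 6.63e-07, and adjusted p = 0.0882 with an estimated correlation). Batf2 and Stat2 (14.9-fold) were again the JAK-STAT members that rose. That list passed camera as higher (adjusted p = 0.0294) although its median was -0.02 and its mean 0.53; adjusted p = 0.133 with an estimated correlation, and 4 rose adjusted over the list alone. That call was lost without either L929 IFNβ array (adjusted p = 0.0889), L929IRF8 untreated replicate 1 (0.0974) or 2 (0.103), or L929IRF8 IFNβ replicate 1 (0.226). The cell cycle list was again lower (median -0.11, adjusted p = 0.00993, adjusted p = 0.106 with an estimated correlation), with 0 members passing and 2 lower adjusted over the list alone. Its median was -0.22 without L929IRF8 untreated replicate 1 and -0.07, not called (adjusted p = 0.319), without replicate 2.

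Clec2e had the largest fall in L929IRF8 also, from 163.1 ± 22.6 to background, at least 6.85-fold. Ahdc1 fell 2.26-fold, Pdgfra, a growth factor receptor of fibroblasts, 2.08-fold, Lpar2 at least 1.98-fold, Chst1 1.91-fold, Hs6st1 1.84-fold, Get1 1.81-fold, Trib2 1.75-fold and Prokr1 1.74-fold. Dvl2 passed with both groups under the background bound.

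Between the lines, 180 probes were called higher with IFNβ in both, against 2.21 for independent lists of these sizes, 23 were called lower in both (0.151 for independent lists), and 0 were called in opposite directions. Of the 125 probes called in L929 alone, 104 had the same sign in L929IRF8, and of the 73 called in L929IRF8 alone, 57 had the same sign in L929. Across the 11411 probes above background, which are not independent replicates, the log2 changes of the lines had a Pearson r of 0.895 and a Spearman rho of 0.487. The log2 changes of the lines share no arrays. The calls are not independent, since the limma fit took each probe's spread from the arrays of all groups. A probe with little spread is thus favoured in both lines, and the counts for independent lists are no exact benchmark for the overlap.

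The comparison named in the series title is that of the lines after IFNβ. Here 1 probe passed in the limma fit. Oas1b (probe ILMN_2613140), a member of the oligoadenylate synthetase family of antiviral genes, read 491.4 ± 12.0 in L929 and 216.3 ± 2.12 in L929IRF8 (SD, n = 2 each). It was 2.27-fold lower in L929IRF8 (log2 change -1.13 ± 0.03, SE, limma adjusted p = 0.00719). All 4 untreated arrays read below 0 for this probe and were set to the floor, where they have no spread and lower the SE. A second Oas1b probe was lower too (log2 change -1.54 ± 0.35) and did not pass (adjusted p = 0.608). The unadjusted p was under 0.05 for 1283 probes, against 1284.9 expected by chance. The Oas1b call was lost with an intensity trend (adjusted p = 0.103), with a replicate block (0.0812) and without any 1 of the 4 untreated arrays (0.0866 to 0.119), over a range of 0.00592 to 0.119 for all alternatives run on it. With the probes above background alone 0 probes passed in limma, and 346 had an unadjusted p under 0.05, against 570.6 expected by chance. That count is below chance, so the 0 calls do not show that the lines are alike. With the replicate block 16 probes passed.

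Several interferon-induced genes had lower values in L929IRF8 than in L929 after IFNβ without passing. Gbp2 read 719.8 ± 92.1 against 2880 ± 550, a 3.98-fold difference (log2 -1.97 ± 0.49, adjusted p = 0.683), and Gbp2b 824.8 ± 204 against 2900 ± 586, 3.53-fold (adjusted p = 0.355). The SE of Gbp2 takes in its untreated arrays, which lay near or under background, varied from 4.00 to 5.375 in log2 value and widen it. After IFNβ the Gbp2 arrays read 11.682 and 11.292 in L929 and 9.645 and 9.39 in L929IRF8. The log2 differences were -1.87 ± 0.50 for Oas2, -1.31 ± 0.21 for Trim21, -1.16 ± 0.13 for Isg20, -1.28 ± 0.21 for Batf2, -1.31 ± 0.32 for Gbp3 and -1.32 ± 0.50 for Tgtp1. In each of these the difference was negative under both replicate numbers. Other differences were smaller: Usp18 read 16180 ± 627 in L929 and 12920 ± 2040 in L929IRF8 (log2 -0.33), and Oasl2 6634 ± 249 and 5806 ± 760 (log2 -0.20). Pdgfra read 107.7 ± 6.08 in L929IRF8 and 236.2 ± 24.4 in L929 (2.19-fold, adjusted p = 0.167). The other genes with the smallest p in either direction, Olfr802, Mtm1, Rundc3a, Msc, Bglap, Serpina9, Olfr348, Adgre1 and Tceal1, lay under the background bound in both groups.

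By camera at the preset correlation, 3 lists were lower in L929IRF8 than in L929 after IFNβ (adjusted p = 3.08e-09, 1.99e-06 and 0.014 for the lists in the order they follow). With the replicate block 6 lists were called. None of the 3 calls held with an estimated correlation (adjusted p = 0.421 for each), and fry gave an adjusted p of 0.157 for each. For nucleic acid and pattern sensing the estimated correlation was -0.013, under the preset 0.01, so that loss does not come from correlation. The ISGF3 antiviral genes had a median log2 difference of -0.33 (-0.28 under replicate 1 and -0.34 under replicate 2), with 33 of 41 members lower, 1 of which (Oas1b) passed and 4 of which passed adjusted over the list alone (Trim21, Isg20, Oas1b and Oas1a). The GBP and IRG GTPases had a median of -0.44 (-0.51 and -0.43), with 17 of 18 members lower, 0 passing over all probes and 6 adjusted over the list alone (Gbp2, Gbp2b, Gbp3, Gbp7, Gbp9 and Gm4841). Nucleic acid and pattern sensing genes had a median of -0.22 (-0.17 and -0.27), with 18 of 23 lower and 0 passing on either count. With values raised to the background bound the medians were -0.25, -0.37 and -0.21. The ISGF3 median was -0.17 without L929 IFNβ replicate 1 and -0.18 without L929IRF8 IFNβ replicate 2, and the sensing list was not called without either of these arrays (adjusted p = 0.404 and 0.198); its median was -0.14 without L929IRF8 IFNβ replicate 1.

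**Figure D2:**
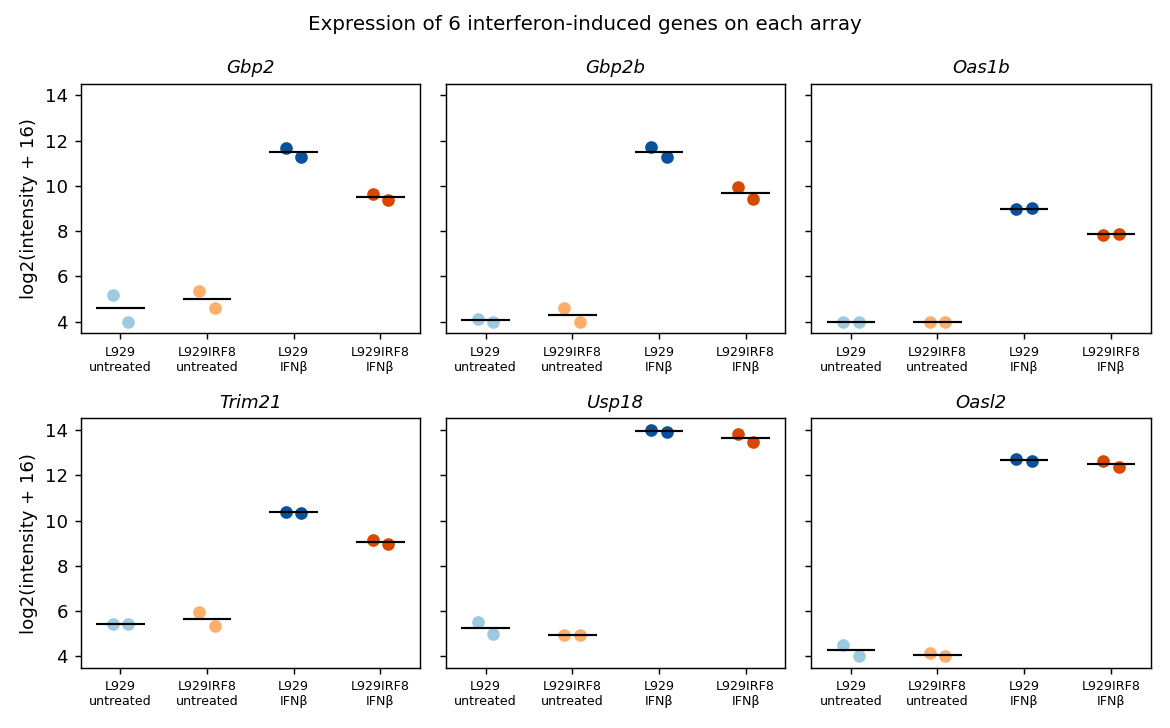
Values of 6 interferon-induced genes, as log2 of the intensity plus 16 (y axis), on each array (points) in the 4 groups, with group means as lines; the 6 genes were picked for the plot after their values were seen. After IFNβ, Gbp2, Gbp2b, Oas1b and Trim21 lie lower in both L929IRF8 arrays than in both L929 arrays, with mean intensities of 719.8 against 2880 for Gbp2, and Usp18 and Oasl2 lie closer together.

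The interaction asks whether the lines' responses to IFNβ differ. Oas1b was again the 1 probe called (interaction -1.13 ± 0.04 on the log2 scale, adjusted p = 0.0363), which repeats the difference after IFNβ, since the untreated values of both lines stand at the floor. That call was lost with median centring (adjusted p = 0.107), an intensity trend (0.241), a replicate block (0.291) and without L929IRF8 untreated replicate 1 (0.0561), over a range of 0.016 to 0.291 for all alternatives run on it. The unadjusted p was under 0.05 for 1226 probes. By camera at the preset correlation the IFNβ response was smaller in L929IRF8 for the GBP and IRG GTPases (median -0.61, adjusted p = 0.000419), the ISGF3 antiviral genes (median -0.11, adjusted p = 0.00169) and MHC class I presentation (median -0.28, adjusted p = 0.0024). With an estimated correlation, each list had an adjusted p of 0.687. Without 1 array these medians ranged from -0.20 to -0.84, from -0.041 to -0.38 and from -0.098 to -0.52. For MHC class I presentation the lines' medians differed by 0.17 in untreated cells, higher in L929IRF8, and by -0.16 after IFNβ (adjusted p = 0.235 and 0.2). With values raised to the background bound the interaction medians were -0.51, -0.20 and -0.29. None of the 3 was called without L929IRF8 untreated replicate 1, L929 IFNβ replicate 1 or L929IRF8 IFNβ replicate 2 (adjusted p from 0.0664 to 0.384), and without L929 untreated replicate 2 the ISGF3 and MHC class I lists were not called (0.275 for both). Members lower in the interaction numbered 15 of 18, 29 of 41 and 17 of 21, and 1, Oas1b, passed on its own, over all probes and adjusted over the list alone.

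The comparison of the lines in untreated cells asks how they differ without interferon. The limma fit called 4 probes, all of them under the background bound on every array: Lrrc75b, Htr5a and a probe with no symbol were lower, the last named after its values were seen, and a second, non-representative probe of Ccdc142, named after its values were seen, was higher in L929IRF8. Over all probes 1419 had an unadjusted p under 0.05. The count was 150 to 264 without any 1 of the 4 untreated arrays and 0 without any 1 of the IFNβ arrays. In the fit of probes above background 0 passed in limma and 424 had an unadjusted p under 0.05, against 570.6 expected by chance. Of the 22 lists 0 passed camera (smallest adjusted p = 0.235, for MHC class I presentation). IRF8-activated genes of myeloid cells had a median change of -0.09 (adjusted p = 0.58), with 0 of 18 passing on either count. The most distant members of the fibroblast and matrix list were Col3a1, with a collagen message 1.78-fold lower in L929IRF8 (log2 -0.80 ± 0.11, adjusted p = 0.339), and Pdgfra, 1.51-fold lower (adjusted p = 0.35). These 2 passed adjusted over the list alone. Of the genes with the smallest p that did not pass, Kctd12b alone lay above background, at 49.3 ± 0.354 in L929IRF8 and 81.5 ± 2.40 in L929 (adjusted p = 0.133); Myod1, Mcidas, Notch3, Cdx4, Nyap2, Calml3, Dock11, Krtap21-1 and Krt26 lay under the bound in both groups.

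Markers of other cell types did not pass as groups with IFNβ in L929: the camera adjusted p was 0.187 for myeloid, 0.287 for lymphoid and 0.266 for epithelial and endothelial markers, with 1, 0 and 1 members risen. Of these lists 5 of 20, 1 of 14 and 3 of 17 members had a mean above background, as did 3 of the 11 MHC class II genes. Most members could thus hardly show a fall, whereas a rise from background was measurable on these arrays, as for Rsad2. The marker genes that rose were Adgre1, with both groups under the background bound, and Esrp1 (at least 2.83-fold). Adjusted p-values in the same comparison were 0.169 for MHC class II presentation, 0.711 for IRF8-activated genes of myeloid cells, 0.603 for fibroblast and matrix genes, 0.0791 for apoptosis, 0.301 for NF-kB targets and 0.659 for unfolded protein and amino acid stress. They were 0.389 for cholesterol synthesis, 0.948 for glycolysis and hypoxia, 0.463 for immediate early genes, 0.471 for p53 targets and 0.12 for housekeeping genes. Members that rose in these lists, beside the apoptosis genes and Il6 named above, were Pml (3.63-fold), a nuclear body protein listed among the IRF8-activated genes, and Mmp2, a matrix metalloproteinase (at least 4.67-fold). In L929IRF8 the lists that did not pass had adjusted p-values of 0.105 to 0.992, with Pml (3.81-fold) and Mmp2 (at least 2.81-fold) among the members that rose. After IFNβ, the 19 lists that did not pass between the lines had adjusted p-values of 0.2 to 0.998.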

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

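The tests of technical explanations were chosen after the results were seen, as were the comparisons restricted to induced genes and to probes above background.

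The planned test of the difference between the lines' IFNβ effects called 1 gene and 3 lists. For Oas1b the interaction was -1.13 on the log2 scale (adjusted p = 0.0363 in limma). Its 4 untreated arrays were set to the floor, so this value is the difference after IFNβ again, the size of the rises is not known, and the floored arrays lower the SE. For the lists the median differences were -0.608 for the GBP and IRG GTPases, -0.282 for MHC class I presentation and -0.112 for the ISGF3 antiviral genes, and these camera calls were lost with an estimated correlation (adjusted p = 0.687 for each). Without 1 array the medians ranged from -0.20 (without L929IRF8 untreated replicate 1) to -0.84 (without L929IRF8 untreated replicate 2), from -0.098 to -0.52 and from -0.041 to -0.38. For the last 2 lists the ends of the range came without L929 IFNβ replicate 1 and without L929IRF8 IFNβ replicate 1.

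Among 252 interferon-induced genes whose IFNβ effect averaged over both lines was at least 1 on the log2 scale, 174 read lower and 78 higher in L929IRF8 than in L929 after IFNβ, with a median difference of -0.17 and a range from -1.97 to 0.82. One factor common to the values of these genes after IFNβ would give log2 differences with no order across genes. The differences of replicate 1 and replicate 2 instead had a Pearson r of 0.756 (95% interval 0.697 to 0.804, brightness trend removed, genes not independent replicates). A response weakened in proportion to each gene's log2 rise would also repeat across replicates, as would differences already present in untreated cells. This r cannot decide on either of those. Fewer responding cells would make each gene's rise in linear intensity one share of its rise in L929, whereas the log2 shares of 224 genes had an r of 0.707 (0.635 to 0.767), and 126 rises were smaller and 43 larger in L929IRF8 under both replicate numbers. One common factor on the values and fewer responding cells are each argued against as the whole cause. The mean level may still differ by chance between cultures, and with 2 arrays against 2 no gap could exclude this. The highest L929IRF8 array exceeded the lowest L929 array in the mean of these genes, a gap of -0.056. That gap sets arrays of different replicate numbers against each other; between arrays of the same number the mean was lower in L929IRF8 both times (9.09 against 9.30, and 8.75 against 9.03), and with the replicate block 16 probes above background were called after IFNβ in place of 0. The labels do not say that the numbers pair the arrays, so chance stays open, as do, untested, an effect of IRF8 on part of the interferon response, a difference between the lines unrelated to IRF8 and a difference in dose or timing that acts unequally on genes.

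The counts between the lines grew where an array of the comparison was left out, to 264 probes in untreated cells without L929IRF8 replicate 2. A candidate explanation is the floor at 0, where values show almost no spread: of 810 calls in the 4 fits that each lack an untreated array, 95.8% lay on probes at or below background, which are 55.6% of all probes. With the probes above background alone, limma called 0 probes in each of the 8 fits. The 4 calls in untreated cells are of the same kind, and no biological explanation was tested for them.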

How the results depend on the processing

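The fits restricted to probes above background or to interferon-induced genes, and the averaged line difference, were added after the data were seen. The IFNβ counts of 328 and 276 probes stayed within 1.5 times under median centring, the offset of 1, the trend, probes at or above the median in brightness, 1 probe per gene and the replicate block; of 85 calls of named genes, 3 were lost with median centring, 8 with the offset of 1, 4 with the trend, 14 with the block and 18 to 26 without 1 array, and 0 changed sign under these. They fell to 9 and 1 with only the groups compared, where 2 residual degrees of freedom remain. With at least 2-fold they were 213 and 182. Similar counts hid turnover: at the offset of 1, 262 of 331 calls in L929 and 212 of 279 in L929IRF8 were shared with the main fit. Of these calls, 115 and 102 lay at or below background. Where leaving out 1 array raised the IFNβ counts, most calls lay at or below background and were not among the main calls. Leaving out 1 array gave 217 to 469 probes in L929 (217 without either untreated L929IRF8 array, 469 without L929 untreated replicate 2) and 135 to 526 in L929IRF8 (135 without either untreated L929 array, 152 without either L929 IFNβ array, 454 without L929IRF8 IFNβ replicate 1, 492 without L929IRF8 untreated replicate 2, 526 without L929IRF8 IFNβ replicate 2); a lone array was assumed to vary like the other groups. Above background the ranges were 240 to 359 (main count 371) and 212 to 295 (main count 324). The 4, 1 and 1 calls of untreated cells, of the lines after IFNβ and of the interaction became 45, 54 and 64 with the offset of 1, 19, 19 and 11 with the trend, 0 each with probes at or above the median in brightness, and 0 to 264, 0 to 266 and 0 to 142 without 1 array. In untreated cells and after IFNβ the count was 0 without any array outside the comparison and at least 131 without any array in it; in the interaction it was 0 without L929IRF8 untreated replicate 1 and at least 34 without any other. Median centring, which moved arrays by at most 0.00362, gave 0 in untreated cells and 0 in the interaction. Only the groups compared gave 0 in untreated cells and 0 after IFNβ, and 1 probe per gene and the 2-fold requirement 0 in untreated cells. Above background these 3 counts were 0 without any 1 array, with 2 in untreated cells at the offset of 1. Apart from the floor at 0, the cause was not tested. Signal over background limits the genes under the bound of 23.7, for which no fold is given.

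The labels do not say that a replicate number marks a shared batch, so the numbers were not used as pairs. Deviations from group means correlated by 0.224 to 0.285 between same-numbered arrays of different groups. In all 4 groups the second principal component was positive for replicate 1 and negative for replicate 2. A shift shared by replicate number is thus visible in the data, and the main fit counts it as spread within groups. The few calls of that fit between the lines may therefore understate differences. With the replicate block limma called 342 probes in L929 and 292 in L929IRF8, 236 and 191 of them shared with the main calls, and 0 in untreated cells, 0 between the lines after IFNβ and 0 in the interaction, where 2045, 1793 and 1648 had an unadjusted p under 0.05. Above background the block gave 678, 645 and 16 for the IFNβ effects and the lines after IFNβ. Among the induced genes it gave 25 in place of 14, and 10 in place of 1 for the interaction, and 6 in place of 0 for the averaged line difference, which was 1 over all probes. Without 1 array the induced genes gave 1 to 7 and 1 to 3, and the averaged difference 0.

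Of the lists called, 8 in L929 and 8 in L929IRF8 became 4 and 3 with an estimated correlation; without 1 array they were 7 to 9 and 6 to 9. The 3 and 3 called after IFNβ and in the interaction became 0 and 0 with an estimated correlation and 0 and 0 with fry, and 2 to 4 and 0 to 3 without 1 array (0 without L929IRF8 untreated replicate 1, L929 IFNβ replicate 1 or L929IRF8 IFNβ replicate 2). With the block 6 were called after IFNβ and 1 in untreated cells, where leaving out 1 array gave 0 to 1.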

Other observations

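The genes here were chosen after their values were seen. Among 252 interferon-induced genes tested for L929IRF8 against L929 after IFNβ, with adjustment over these genes alone, 13 were lower and 1 was higher in L929IRF8 in limma. Beside Oas1b, Gbp2b, Trim21, Isg20 and Batf2 they include Pstpip1 (log2 difference -1.30 ± 0.13, SE; 381.1 ± 46.1 against 958.5 ± 100, SD), Hdc, the enzyme that makes histamine (-1.29 ± 0.16), Dusp28 (-1.56 ± 0.19), Bnip5 (-1.50 ± 0.16), Apol9b (-0.51 ± 0.07), Oas1a (-0.48 ± 0.08), Rbm43 (-0.58 ± 0.10) and Gm4841 (-0.77 ± 0.13). Serpinb6b, a serine protease inhibitor, was the 1 gene higher (0.71 ± 0.11; 656.8 ± 67.5 against 393.8 ± 36.1). With the replicate block 24 were lower and 1 higher, 13 of them called in both fits. Leaving out any 1 array brought the count to between 1 and 7, the lowest without L929IRF8 IFNβ replicate 2. The immune checkpoint ligand Cd274 read 538.2 ± 303 in L929IRF8 and 1470 ± 110 in L929 and did not pass (adjusted p = 0.176). Mx1 read 1512 ± 761 in L929IRF8 and 1501 ± 161 in L929, Nrap 3072 ± 259 and 2890 ± 635, and Csprs 4549 ± 1333 and 4418 ± 1167.

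The lines were also compared averaged over both treatments. Tested on probes above background, 0 probes passed in limma, and 481 had an unadjusted p under 0.05, against 570.6 expected by chance. With the replicate number as a block 1115 had an unadjusted p under 0.05, and 6 probes passed after adjustment. They are 3 probes of Cd28, a costimulatory receptor known from T cells, 2.27-fold to 2.54-fold higher in L929IRF8, Lpar4, a lysophosphatidic acid receptor, 2.37-fold higher, and Dusp28 and a probe with no symbol, lower. For the last 2 the difference lay in the IFNβ arrays: Dusp28 read 32.9 ± 6.36 in L929 and 24.9 ± 3.68 in L929IRF8 untreated, and 186.4 ± 24.7 and 53.1 ± 13.7 after IFNβ, and the other probe was under background in both untreated groups. For each of the 6 probes all 4 comparisons of same-numbered arrays had the same direction. The block fit that picked them favours such probes, so this is no separate support. For one of the Cd28 probes the means were 151.3 ± 68.3 and 413.4 ± 93.6 in untreated L929 and L929IRF8, and 251.4 ± 70.8 and 631.7 ± 229.1 after IFNβ. The endocytic adaptor Dab2 was 1.73-fold lower on one probe and 1.59-fold lower on the other (adjusted p = 0.084 and 0.091 with the block). No explanation was tested for these values.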
